A study of Siansivirga zeaxanthinifaciens CC-SAMT-1 with 8 samples.

How the data were processed

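Gene expression was measured by strand-specific RNA sequencing in Siansivirga zeaxanthinifaciens CC-SAMT-1, a marine flavobacterium, after depletion of ribosomal RNA, per the labels' protocols. There were 8 libraries from 2 experiments. In the full-spectrum experiment, cultures were kept for 36 h under white fluorescent lamps (2 libraries, L36.1 and L36.2) or in darkness (2 libraries, D36.1 and D36.2). In the colour experiment, cultures kept for 24 h in darkness were lit for 12 h with red, green or blue diodes (1 library each), beside 1 culture kept in darkness for 36 h (D36). Groups and replicate numbers were taken from the sample titles. The design text speaks of duplicates, but 1 library per colour was given, so the colour comparisons had no replicates. Nothing in the labels says whether the numbered libraries came from separate cultures, so p-values measure only the spread between these samples.

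The authors deposited tables of whole-number read counts per gene, not normalised, in 5 comparison tables; the column names of these tables say 37 where the titles say 36, and were matched to the titles on the rest of the name. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trimmomatic 0.35, Bowtie2 2.1.0, HTSeq 0.5.4p2 and DESeq2 1.12.1; their roles, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited tables also hold a normalised signal per library, which equalled the count divided by 1 factor per library, and a log2 ratio per gene, which equalled the log2 of the ratio of those values after adding 1 to each; neither entered a test. The authors' deposited p-values and adjusted p-values were read only to count how many passed 0.05. Counts of a library were identical in all tables of its experiment. There were 2842 genes in the full-spectrum experiment and 2837 in the colour experiment, of which 2835 were in both; none was a ribosomal or transfer RNA, so a fit without such genes did not apply. Gene identifiers and product names were used as the files give them. No genome was used, so positions, operons and reads shared between near-identical copies (such as the several TonB-dependent receptors) were not checked.

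Total counts per library ran from 14355148 to 17632737. Counts of the dark replicates differed more than sampling noise (chi-square per degree of freedom 12.9 over 2782 genes with at least 20 reads), as did those of the light replicates (9.12 over 2784 genes), so each was kept as a library of its own. Intervals given for the colour libraries are exact binomial (Clopper-Pearson) 95% intervals on the reads of 2 libraries and cover counting error only.

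Full-spectrum light was compared with darkness in the 4 libraries of that experiment with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest), with the replicate number as a block because the authors deposited 1 comparison per number. It tested 2791 genes at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. The common coefficient of variation was 5.15%. In counts simulated for this comparison (2785 genes in the fit), 96 of 100 genes changed by 1 on the log2 scale and 87 of 99 changed by 0.5 were called with the right sign, and 8 unchanged genes were called. Pair ratios used TMM-scaled counts plus a pseudocount of 1.

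Each colour library was compared with the dark library of its own experiment without a test. A gene passed the size rule at a log2 ratio of at least 1 in size with at least 50 reads over the 2 libraries, after TMM scaling of the 2 libraries and a pseudocount of 1. In counts simulated for 1 colour library against 1 dark library (2837 genes), 200 of 200 genes changed by 2 on the log2 scale passed, and 1 unchanged gene passed. These changes lay well past the rule, so their passing was built in. The simulation held only the spread between replicates of the full-spectrum experiment. It therefore gives no error rate between separate flasks: 191 and 176 genes passed between unlit libraries of the 2 experiments. Libraries with the same label, and the dark libraries of the 2 experiments, were compared by the same rule as background. Because the 3 colours share 1 dark library, 100 sets of unchanged libraries were simulated from its counts with the fitted dispersions.

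Before the data were examined, 25 gene lists were written as patterns on product names; the list of ribosomal RNA had no member and the other 24 were used. In the full-spectrum comparison they were tested with camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation). In the colours, a list's median was placed among the medians of 10000 random lists of the same size matched on read count. Some patterns took unintended genes. The respiratory list includes a quinolinate synthetase, of NAD synthesis, and the pentose phosphate list a keto-deoxy-phosphogluconate aldolase. The list of glycoside hydrolases and polysaccharide lyases was written to take sulfatases too. The DNA repair list includes enzymes with pyruvate in their names, the tricarboxylic acid cycle list 3-isopropylmalate dehydrogenases, and the type IX secretion list mostly secreted proteins with its targeting domain. Genes are named by a rule fixed at the same time. It took the 10 largest rises and falls with an informative product under full-spectrum light that passed the test with the same sign in both pairs, and the 8 largest each way past the size rule in each colour. It added the largest members of each list described, all photolyase and carotenoid genes, and the genes past the rule in all 3 colours. Genes chosen otherwise are said to be so.

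Alternatives were no replicate block, DESeq2 1.42.0, median-of-ratios scaling, other count filters, a 2-fold minimum, each library left out, other read minimums, sizes, scalings and pseudocounts for the colours, and other dark libraries as control.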

Results

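The series asked how full-spectrum light and light of single colours change gene expression, with carbon metabolism as its stated subject, in a heterotrophic flavobacterium that carries zeaxanthin genes. Cultures of 200 ml marine broth grew at 25 °C for 36 h in all. Full-spectrum light had a flux of 31 µmol photons per square metre and second and was given for the whole period. Red (620 to 630 nm), green (520 to 535 nm) and blue (465 to 485 nm) light had a flux of 37 and was given for the last 12 h. There were 2 full-spectrum libraries (15637516 and 15137579 counts) with 2 dark libraries (16135476 and 17632737). The colour experiment had 1 library each for red (15309694), green (14355148), blue (16005309) and darkness (15222854). At this depth the median gene had between 1263 and 1453.5 reads in a library.

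Full-spectrum light was first compared with darkness over 36 h. The gene with the largest rise was AW14_RS11165, a UDP-2,3-diacylglucosamine hydrolase (an enzyme of lipid A synthesis), from 8.89 ± 0.325 CPM (edgeR's count unit, scaled to library size) in darkness to 805 ± 1.33 in light (SD, n = 2 each), a 90.5-fold rise. The TonB-dependent receptors AW14_RS03935 and AW14_RS03940, outer membrane proteins that take up large or scarce nutrients, rose 27.2-fold and 9.25-fold. The cytochrome C peroxidase AW14_RS10370, which reduces hydrogen peroxide, rose 19.7-fold. The largest fall was that of AW14_RS03950, a nicotinic acid mononucleotide adenyltransferase of NAD synthesis, from 1470 ± 20.9 to 56.1 ± 1.23 CPM (SD, n = 2 each), a 26.2-fold fall.

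Other large rises included the glycosyltransferase AW14_RS02090 (9.22-fold), the response regulator AW14_RS02100 (5.51-fold) and the sensor histidine kinase AW14_RS02095 (5.39-fold). The anhydro-N-acetylmuramic acid kinase AW14_RS01510, of cell wall recycling, rose 4.89-fold, the phosphate:sodium symporter AW14_RS03960 3.59-fold and the FAD-binding protein AW14_RS11160 3.51-fold. Among the falls, the universal stress protein AW14_RS06955 was 4.57-fold lower, the ATPase AW14_RS07015 4.24-fold, acetate kinase AW14_RS06010, which makes ATP and acetate from acetyl phosphate, 4.01-fold, and a further TonB-dependent receptor, AW14_RS04965, 3.76-fold. Ribonucleoside-diphosphate reductase AW14_RS14105, which makes deoxyribonucleotides, fell 3.32-fold, porphobilinogen deaminase AW14_RS03175, of heme synthesis, 3.07-fold and the peptidase AW14_RS02530 3.01-fold. AW14_RS07000 (cytochrome C oxidase subunit IV) and AW14_RS10660 (a transcriptional regulator) completed the 10 largest falls with an informative product, and were less certain. AW14_RS07000 had only 1.34 ± 0.704 CPM in darkness (SD, n = 2). AW14_RS10660 fell by 4.08 on the log2 scale in pair 1 and by 0.92 in pair 2. In edgeR's quasi-likelihood test, AW14_RS07000 lost the call without dark replicate 1 (adjusted p = 0.171) and without light replicate 2 (adjusted p = 0.102). AW14_RS10660 lost it without dark replicate 1 (edgeR adjusted p = 0.0927), without dark replicate 2 (adjusted p = 0.122) and in DESeq2 (adjusted p = 0.124). With the colour experiment's dark library added to the dark group and no replicate block, neither was called (edgeR adjusted p = 0.237 and 0.454), nor were the receptors AW14_RS03935 (0.0903) and AW14_RS03940 (0.161), the ATPase AW14_RS07015 (0.125) or AW14_RS03175 (0.116).

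In all, edgeR's quasi-likelihood test called 1365 of 2791 genes (48.9%) at an adjusted p under 0.05, 690 higher and 675 lower in light, with a median size of 0.37 on the log2 scale. At least 2-fold changes were found in 54 genes that rose and 72 that fell. The 2 pairs, taken as ratios, moved 96 of 2769 genes by at least 2-fold in the same direction (44 higher, 52 lower) and none in opposite directions; 3.27 such genes would be found if the pairs were independent. Scaling by total reads moved the median of all genes by 0.168 on the log2 scale and the calls to 1189 higher and 317 lower (79% higher, against 690 of 1365), so directions of small changes are relative to the TMM scaling. Adding the dark library of the colour experiment to the dark group and dropping the replicate block, 2 changes at once, left 134 calls, 67 each way. Of 89 genes named in this text, 46 lost the call and a further 7 turned in sign. The authors' deposited tables, made for 1 light and 1 dark library at a time, had no gene with an adjusted p under 0.05 in either pair, 11 and 0 genes with an unadjusted p under 0.05, and listed 150 and 112 candidate genes.

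**Figure D1:**
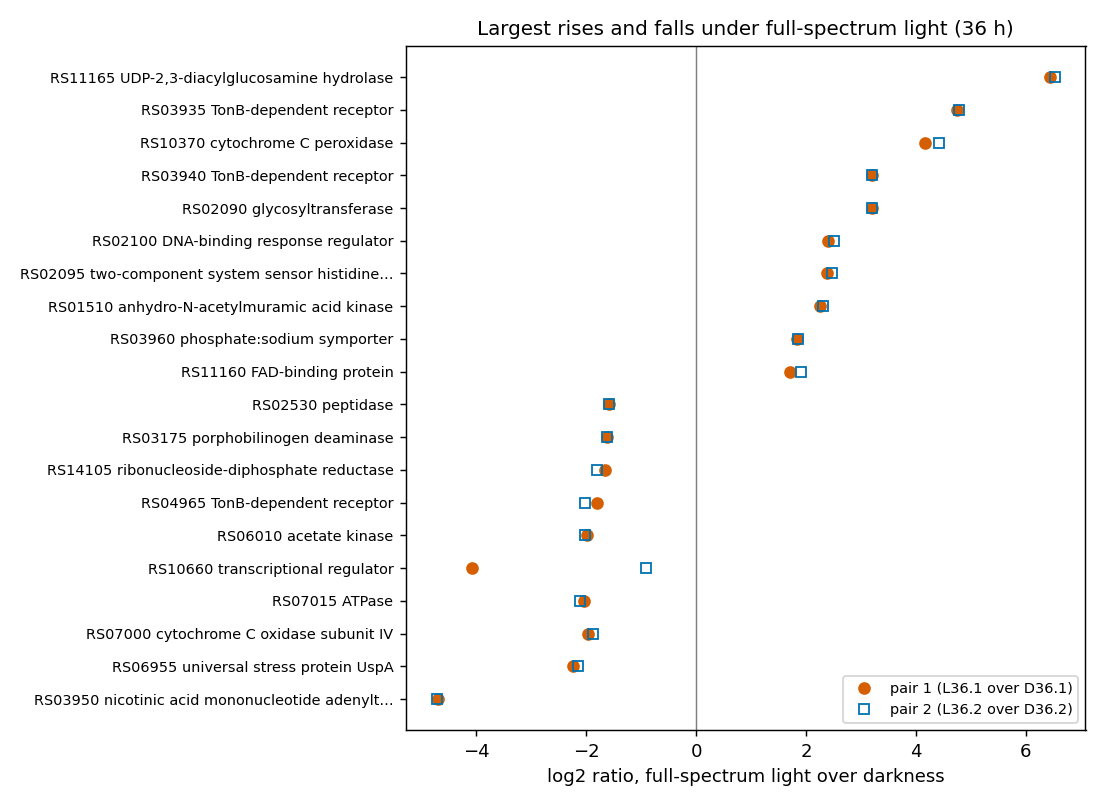
Log2 ratio of full-spectrum light over darkness (x axis) in pair 1 (circles) and pair 2 (squares) for the 10 largest rises and 10 largest falls with an informative product (y axis, locus tags without their AW14_ prefix). The pairs lie close together except for AW14_RS10660, at -4.08 and -0.92.

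Gene lists were examined next under full-spectrum light. Of 25 measured genes of the respiratory chain and ATP synthase, 10 fell, 7 rose and 8 did not pass. Besides AW14_RS07000, the largest falls were those of the cbb3-type cytochrome oxidase subunit AW14_RS07005 (2.73-fold), of a terminal oxidase with high oxygen affinity, and of nearby identifiers. These were the cytochrome C oxidase subunits AW14_RS06995 (2.8-fold) and AW14_RS06990 (2.13-fold) and the Cbb3 oxidase maturation protein CcoH, AW14_RS06985 (2.58-fold). With the colour experiment's dark library added and no block, all were still lower but none was called. Their edgeR adjusted p-values were 0.0594 (AW14_RS07005), 0.0988 (AW14_RS06995), 0.196 (AW14_RS06990) and 0.215 (AW14_RS06985). The camera test placed the list lower than other genes (adjusted p = 0.0381; adjusted p = 0.864 with an estimated correlation), and its median of -0.10 turned to 0.06 with total-read scaling. Of 58 genes with ribosomal protein names, 34 fell, 10 rose and 14 did not pass. Their median was -0.24, or -0.070 with total-read scaling (camera adjusted p = 0.000691, and adjusted p = 0.864 with an estimated correlation). AW14_RS09465, which the files name 30S ribosomal protein S30, fell 2.3-fold and S4 (AW14_RS01065) 2.17-fold. L30 (AW14_RS01095) was 2.8-fold lower from 3.58 ± 1.15 CPM in darkness (SD, n = 2). Of 39 genes of SusC, SusD and TonB-dependent uptake, 19 rose, 7 fell and 13 did not pass (camera adjusted p = 0.0381, higher, and adjusted p = 0.864 with an estimated correlation). Without the replicate block, camera still called the ribosomal proteins (adjusted p = 0.00129). The respiratory, uptake, photolyase and nitrogen and sulfur lists then lost the call (camera adjusted p = 0.0509 each). Of the 5 lists that camera called, the ribosomal proteins kept the call with each library left out in turn. The respiratory list and the photolyases lost it without light replicate 1 (camera adjusted p = 0.0538 and 0.0616) and without light replicate 2 (0.0915 each). The uptake list lost it without dark replicate 1 (camera adjusted p = 0.118), dark replicate 2 (0.0852) and light replicate 1 (0.0514). Nitrogen and sulfur assimilation lost it without dark replicate 2 (camera adjusted p = 0.0679), light replicate 1 (0.0616) and light replicate 2 (0.0553).

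All 3 photolyases, enzymes that repair ultraviolet damage in DNA with light energy, rose (AW14_RS09660 by 1.56-fold, AW14_RS09665 by 1.53-fold and AW14_RS09610 by 1.32-fold; camera adjusted p = 0.0381, and adjusted p = 0.864 with an estimated correlation). None of the 3 was called with the colour experiment's dark library added and the replicate block dropped (edgeR adjusted p = 0.136, 0.175 and 0.0909). In that fit they stayed higher in light, with log2 fold changes of 0.52, 0.47 and 0.46. Of 12 genes of carotenoid and isoprenoid synthesis, 3 rose and 9 did not pass. Lycopene cyclase AW14_RS13780 rose 1.28-fold and diapophytoene dehydrogenase AW14_RS06835 1.21-fold. With the colour experiment's dark library added and no block, neither was called (edgeR adjusted p = 0.132 and 0.159). The largest log2 fold change of the list was 0.43. Polyprenyl synthetase AW14_RS06085 had 91.4 and 93.9 TMM-scaled CPM in darkness, 124 and 125 in full-spectrum light and 103 in the colour experiment's dark library. Phytoene dehydrogenase AW14_RS13765 had a log2 fold change of 0 (SE 0.046), phytoene synthase AW14_RS13770 of -0.11 (SE 0.061) and beta-carotene hydroxylase AW14_RS13775 of 0.02 (SE 0.058). Without light replicate 2, phytoene synthase passed as lower (log2 fold change -0.23, edgeR adjusted p = 0.0235).

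In nitrogen and sulfur assimilation, 4 of 14 genes rose, 2 fell and 8 did not pass (camera adjusted p = 0.0381, higher; adjusted p = 0.864 with an estimated correlation). The risers were neighbouring identifiers of sulfate reduction, including sulfate adenylyltransferase AW14_RS05940 (3.33-fold) and AW14_RS05945, named nitrite reductase (2.53-fold), while the ammonium transporter AW14_RS04095 fell 2.11-fold. In porphyrin and heme synthesis, 6 of 14 rose and 4 fell. Coproporphyrinogen III oxidase AW14_RS06950 fell 2.26-fold, the log2 level of glutamyl-tRNA reductase AW14_RS03170, the entry enzyme of the pathway, fell by 0.66, and protoporphyrinogen IX oxidase AW14_RS03140 rose 1.69-fold. The reductase had 307 TMM-scaled CPM in the colour experiment's dark library, below both light libraries (332 and 336). With that dark library added and no block, none of these genes was called (edgeR adjusted p = 0.128 for AW14_RS06950, 0.387 for AW14_RS03170 and 0.288 for AW14_RS03140). In iron uptake, 4 of 7 rose and 3 fell, led by the ferrous iron transporters AW14_RS02910 (2.02-fold lower) and AW14_RS02915 (1.99-fold lower). The iron ABC transporter AW14_RS14090 was 1.32-fold higher, but had a log2 ratio of 0.02 in pair 1 and 0.78 in pair 2; without light replicate 2 its log2 fold change was 0.02 (edgeR adjusted p = 0.84), and without dark replicate 1 or 2 its adjusted p was 0.159 or 0.174. In oxidative stress defence, 6 of 24 rose and 9 fell. Superoxide dismutase AW14_RS06945 rose 1.68-fold and thioredoxin AW14_RS02245 fell 2.14-fold. The dismutase had 879 TMM-scaled CPM in the colour experiment's dark library, above both light libraries (782 and 735). With that dark library added and no block, the dismutase had a log2 fold change of 0.35 (edgeR adjusted p = 0.566). Among 53 sensor kinases, response regulators and sigma factors, 18 rose and 14 fell (camera adjusted p = 0.0907), and all 5 changes of at least 2-fold were rises, sigma factor AW14_RS06105 among them (2.89-fold).

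In central carbon metabolism, 3 of 13 genes of glycolysis and gluconeogenesis rose and 6 fell (camera adjusted p = 0.421). Phosphoenolpyruvate carboxykinase, AW14_RS09785, of gluconeogenesis and an abundant transcript, fell 2.32-fold from 35800 ± 516 to 15400 ± 462 CPM (SD, n = 2 each). Of 20 genes in the tricarboxylic acid cycle list, 3 rose and 6 fell, with malate dehydrogenase AW14_RS08385 1.71-fold lower. Of 15 genes of the glyoxylate shunt and carbon dioxide fixing enzymes, 3 rose and 6 fell. A biotin carboxyl carrier subunit, AW14_RS01690, fell 2.5-fold, but had 23.4 TMM-scaled CPM in the colour experiment's dark library, below both light libraries (29.5 and 25.7). With that dark library added and no block, AW14_RS01690 was not called (edgeR adjusted p = 0.326). In the pentose phosphate pathway 3 of 8 rose and 4 fell, with ribulose-phosphate 3-epimerase AW14_RS07875 2.35-fold lower. Methylcrotonoyl-CoA carboxylase AW14_RS01700, of leucine breakdown, fell 2.61-fold among 8 falls and 4 rises in 26 genes of amino acid degradation, and glutamine synthetase AW14_RS14125 fell 1.93-fold among 14 falls and 20 rises in 57 genes of amino acid synthesis. Of 54 genes in the list of glycoside hydrolases and polysaccharide lyases, which also takes sulfatases, 6 rose and 7 fell. Sulfatase AW14_RS08680 rose 2.02-fold and beta-glucanase AW14_RS05580 1.8-fold. The sulfatase had 555 TMM-scaled CPM in the colour experiment's dark library, above both light libraries (462 and 472). With that dark library added and no block, neither the sulfatase nor the glucanase was called (edgeR adjusted p = 0.566 and 0.318). Of 55 genes with type IX secretion or gliding names, 21 rose and 7 fell, with the secreted protein AW14_RS14530 2.27-fold lower.

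The remaining lists showed changes both ways, and camera called none of them, nor the carbon, amino acid, porphyrin, iron, oxidative stress, hydrolase, type IX or carotenoid lists. Peptidases had 17 rises and 31 falls in 87 genes, chaperones 4 and 7 in 20, DNA repair 7 and 9 in 36, fatty acid and phospholipid synthesis 2 and 6 in 19, fatty acid beta-oxidation 2 and 5 in 9, and mobile elements and phage 3 and 4 in 24. Adjusted over the list alone, the ribosomal proteins had 10 rises and 35 falls, the uptake list 20 and 7, the hydrolases 5 and 2, peptidases 17 and 34, chaperones 4 and 8, amino acid synthesis 20 and 16, sensors and sigma factors 18 and 15, DNA repair 6 and 9, and mobile elements 2 and 3. The counts of the other 15 lists were the same adjusted over the list alone. The median and the camera direction differed in sign for the iron list (median 0.24, mean -0.14, lower in camera), DNA repair (0.02, -0.02, lower), amino acid synthesis (-0.04, 0.02, higher) and the sensor list (0.00, 0.19, higher). With an estimated correlation, which rests on 1 residual degree of freedom, camera called no list.

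**Figure D2:**
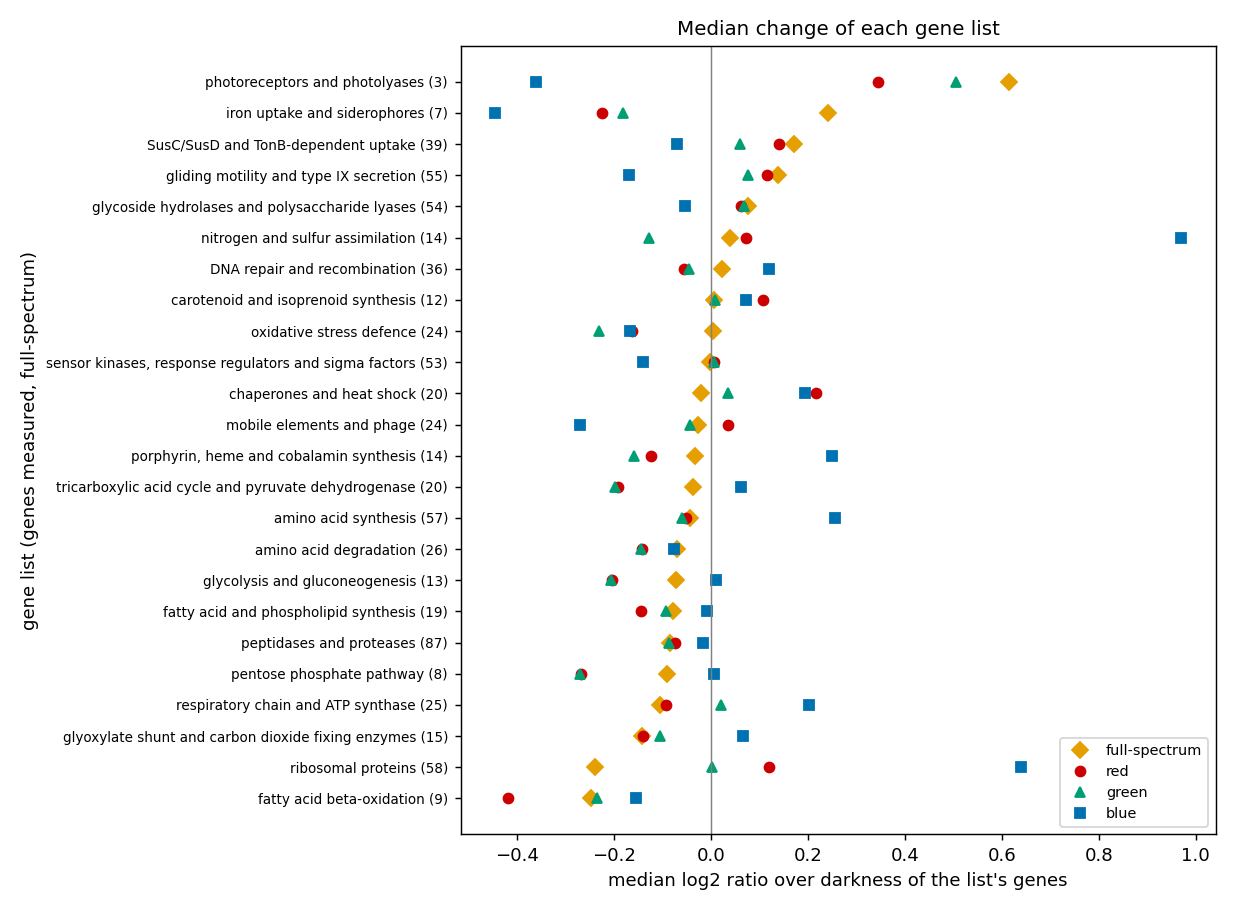
Median log2 ratio over darkness (x axis) of the 24 gene lists (y axis, with the number of genes measured under full-spectrum light) for full-spectrum light (diamonds, 2 libraries per group), red (circles), green (triangles) and blue (squares, 1 library per colour, over the colour experiment's dark library). Ribosomal proteins lie at -0.24 under full-spectrum light and 0.64 under blue, and nitrogen and sulfur assimilation at 0.97 under blue (10 genes with at least 50 reads).

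Red light was compared with darkness with 1 library each, so no difference has a replicate check. The genes with an informative product and the largest ratios after red light were the 2 TonB-dependent receptors, the hydrolase AW14_RS11165 and the peroxidase, which also led under full-spectrum light. AW14_RS03935 had 20092 reads against 24 in darkness (log2 ratio 9.48, counting interval 8.96 to 10.17), AW14_RS03940 had 48360 against 170 (7.97, 7.76 to 8.20) and AW14_RS10370 17634 against 133 (6.86, 6.63 to 7.13). The hydrolase AW14_RS11165 had a log2 ratio of 7.89, the glycosyltransferase AW14_RS02090 of 3.90, the porin AW14_RS03955 of 3.09 and sigma factor AW14_RS06105 of 2.77. Lowest among genes with an informative product were the universal stress protein AW14_RS06955 (-3.51), the transporter AW14_RS09825 (-3.41), the ferrous iron transporters AW14_RS02910 (-3.16) and AW14_RS02915 (-2.82), coproporphyrinogen III oxidase AW14_RS06950 (-2.97) and the adenyltransferase AW14_RS03950 (-2.95). The universal stress protein AW14_RS07030 (-2.80) and the Crp/Fnr family regulator AW14_RS07035 (-2.76) followed. At the 2 receptors the other experiment's dark libraries lay above the colour experiment's by 5.10 and 4.74 on the log2 scale. The red ratios over the mean of all 3 dark libraries were 6.09 for AW14_RS03935, 4.82 for AW14_RS03940 and 6.81 for AW14_RS11165, then the highest of these. Under red light 141 genes passed the size rule, 68 higher and 73 lower.

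Green light gave a similar order against the same dark library. AW14_RS03935 had a log2 ratio of 8.29 (counting interval 7.77 to 8.99), AW14_RS03940 of 7.45, AW14_RS11165 of 6.83 and AW14_RS10370 of 5.94. Over the mean of all 3 dark libraries these were 4.91, 4.31, 5.76 and 4.09, with AW14_RS11165 the highest of the 4. Lowest among genes with an informative product were AW14_RS09825 (-3.64), AW14_RS06955 (-3.19), AW14_RS06950 (-3.14), AW14_RS07030 (-2.99), AW14_RS07035 (-2.94), AW14_RS02910 (-2.63), AW14_RS02915 (-2.58) and phosphate acetyltransferase AW14_RS06015 (-2.33), the partner of acetate kinase. Phosphoenolpyruvate carboxykinase AW14_RS09785 had -2.05. Under green light 75 genes passed, 31 higher and 44 lower.

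Single genes and lists differed from the dark library of the colour experiment in these 2 libraries. The cbb3-type oxidase subunit AW14_RS07005 had log2 ratios of -1.79 (red) and -1.74 (green), and 4 (red) and 3 (green) of 24 respiratory genes passed the rule, all lower; the list lay at percentiles of 33.0 in red (median -0.092) and 91.2 in green (median 0.020). The tryptophan synthase genes AW14_RS00880 and AW14_RS00870 had -1.54 and -1.21 in red and -1.21 and -1.06 in green; over the mean of all 3 dark libraries AW14_RS00870 had -0.99 and -0.83. In red, GroES AW14_RS06245 had 1.18 and the heat-shock protein AW14_RS03925 2.35, and the median of 20 chaperones lay at the 99.2 percentile of matched random lists (green, 87.6). The uptake list lay at the 98.9 percentile in red and the 96.7 in green, and the photolyases at 94.8 and 99.8 (medians 0.34 and 0.51). The ribosomal proteins lay at 99.3 in red (median 0.12) and 83.7 in green, and the type IX list at 97.7 and 96.2. Low lists were fatty acid beta-oxidation in red (percentile 0.995) and, in green, oxidative stress defence (0.45) and the pentose phosphate pathway (2.28). Lists also lay far out between unlit libraries. In D36.1 and D36.2 over D36, the ribosomal proteins lay at 100 and the respiratory list at 99.63. Chaperones lay at 0.44, the hydrolases at 0.41 and the type IX list at 0.18. The other lists lay less far out, among them uptake at 2.605 and the photolyases at 12.22. An extreme percentile alone therefore does not set light apart from a difference between flasks. Several of the red and green placements turned with the control. With the mean of all 3 dark libraries as control, the ribosomal proteins lay at percentiles of 0.04 in red (median -0.27) and 0 in green (median -0.34), and beta-oxidation in red at 89.4 (median 0.23). The respiratory list lay at 5.725 in red and 5.22 in green (medians of -0.22 each). In green, oxidative stress defence lay at 17.96 and the pentose phosphate pathway at 49.6. The uptake list lay at 99.7 in red and 99.9 in green and the type IX list at 99.7 and 99.99. Carotenoid genes showed no ratio past the rule in any colour, with medians of 0.11 (red), 0.01 (green) and 0.07 (blue).

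Blue light gave other leading genes. Highest among genes with an informative product were the ATPase AW14_RS07015 (log2 ratio 2.28, counting interval 2.26 to 2.30), sulfate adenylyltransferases AW14_RS05935 (2.20) and AW14_RS05940 (1.94), phosphoadenylylsulfate reductase AW14_RS05930 (2.04) and the nitrogen regulator P-II AW14_RS04100 (1.87). The transporter AW14_RS00280 (1.79), the ammonium transporter AW14_RS04095 (1.77) and the lipid-binding protein AW14_RS09940 (1.77) followed. Lowest among these were a run of identifiers with the RND transporter AW14_RS12650 (-3.59), sulfide:quinone reductase AW14_RS12620 (-2.91), AcrB-type transporter AW14_RS12655 (-2.66), transporter AW14_RS12645 (-2.51), methyltransferase AW14_RS12605 (-2.45), sulfurtransferase AW14_RS12585 (-2.20) and thioredoxin AW14_RS12600 (-1.82), and the TonB-dependent receptor AW14_RS02750 (-2.27). The peroxidase AW14_RS10370 and the receptors AW14_RS03935 and AW14_RS03940 had -0.40, 0.65 and 0.01. Over the mean of all 3 dark libraries AW14_RS07015 had 1.32, AW14_RS05940 1.55, then the highest of those listed, AW14_RS12650 -1.94 and AW14_RS02750 -2.80, then the lowest, while AW14_RS12585 (-0.99), AW14_RS12600 (-0.70) and AW14_RS00280 (0.87) no longer passed. Under blue light 84 genes passed, 42 each way.

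By list, 5 of 10 nitrogen and sulfur genes passed as higher in blue (median 0.97, percentile 100). Besides the ammonium transporter AW14_RS04095, these were neighbouring identifiers (AW14_RS05930, AW14_RS05935, AW14_RS05940 and AW14_RS05945). Random lists were matched on read count only, so neighbours that move together can raise this percentile. The 58 ribosomal proteins had a median of 0.64 (percentile 100), S21 (AW14_RS00640, 1.51) and L10 (AW14_RS00575, 1.18) among the 4 past the rule (0.61 and 0.94 over the mean of all 3 dark libraries). The 57 amino acid synthesis genes had a median of 0.26 (percentile 100). The iron, mobile element, type IX and sensor lists lay low, at percentiles of 0.555, 0.245, 0.24 and 0.53, and the respiratory, porphyrin and chaperone lists at 98.6, 98.3 and 97.6. Most of these placements were lost or turned against the mean of the other experiment's dark libraries. The ribosomal proteins had a median of 0.055 (percentile 70.1), with none higher and 2 lower past the rule, and the type IX list lay at 97.9 (median 0.13), sensors at 75.5, iron at 45.65, porphyrin at 81.3 and the respiratory list at 12.65 (median -0.068). Nitrogen and sulfur (median 0.83, percentile 100), amino acid synthesis (99.98), mobile elements (0.07) and chaperones (99.7) stayed at the same end. With the mean of all 3 as control, the ribosomal proteins stayed at 100 (median 0.27), nitrogen and sulfur and amino acid synthesis at 100 and mobile elements at 0.05. Chaperones then lay at 87.5, porphyrin at 93.96, iron at 29.3, sensors at 17.3, the respiratory list at 13.97 and the type IX list at 13.2. With a minimum of 10 reads, however, which measures all 14 nitrogen and sulfur genes, their median was 0.14 (percentile 84.96), still with 5 higher past the rule. Superoxide dismutase AW14_RS06945 had -1.16 and cytochrome D ubiquinol oxidase AW14_RS12610 -1.13 over the colour experiment's dark library, but -0.50 and -0.090 over the mean of all 3. The 3 photolyases were all lower in blue than in the colour experiment's dark library (-0.505 to -0.341, median -0.36, percentile 7.44). The other experiment's dark libraries had a similar photolyase median over that library (-0.355, percentile 12.22).

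The background between dark libraries was as large as these colour differences. By the same rule, the 2 dark replicates of the full-spectrum experiment differed at 1 gene and the light replicates at 23, but the dark library of the colour experiment differed from them at 191 and 176 genes, more than the 141, 75 and 84 of red, green and blue. The library labelled blue differed from the same 2 dark libraries at 79 and 81 genes, from red at 273 and from green at 197, so this ranking holds only with the blue and dark labels as given. The ribosomal list lay higher by a median of 0.52 (percentile 100) in those 2 dark libraries than in that of the colour experiment. Of the 84 genes past the rule in blue, 14 also passed in the same direction against both other dark libraries. Total-read scaling moved the median of all genes by 0.169 in red and 0.235 in green and the share of higher genes past the rule from 68 of 141 to 107 of 158 in red and from 31 of 75 to 63 of 96 in green. The authors' deposited tables had no gene with an adjusted p under 0.05 in any colour, 27 (red), 8 (green) and 18 (blue) genes with an unadjusted p under 0.05, and listed 251 (red), 70 (green) and 128 (blue) candidates.

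The colours were then compared with each other, all against the same dark library. In the same direction under all 3 there were 4 genes, 2 higher (porin AW14_RS03955 and AW14_RS05925, a hypothetical protein) and 2 lower (hypothetical proteins AW14_RS14275 and AW14_RS14270). Unchanged libraries simulated against the shared dark library gave a mean of 0.06, and independent lists would give 0.0121 higher and 0.0184 lower. The simulation holds only the spread between replicates of the full-spectrum experiment, not that between flasks of separate experiments. Unlit libraries of the 2 experiments differed at 151 genes with both full-spectrum dark libraries, of which 41 passed in the same direction in blue, 17 in red and 12 in green. Red and green shared 66 genes in the same direction (28 higher, 38 lower) and none in opposite directions, where the simulation gave 0.15 and independent lists 0.779 higher and 1.19 lower. Across 2667 genes, which are not independent replicates, the log2 ratios of red and green had a Pearson correlation of 0.924 and a covariance of 0.337 (simulated 0.509 and 0.0123). Red and blue had -0.03 and -0.00923, and green and blue -0.04 and -0.00899, with the same simulated covariance. With the dark libraries of the full-spectrum experiment as the control of the second colour, the correlation was 0.557 for red and green, -0.31 for red and blue and -0.37 for green and blue. Against the mean of all 3 dark libraries, none of the 4 genes shared by all colours passed in each. Porin AW14_RS03955 had 0.68 in red, 0.00 in green and -0.89 in blue, AW14_RS05925 had 0.80, 0.00 and 1.20, AW14_RS14275 had -2.12, -1.07 and -0.90, and AW14_RS14270 had -1.10, -0.41 and -0.75.

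Against full-spectrum light, which has its own dark libraries, the Pearson correlation across 2803 genes was 0.612 for red, 0.575 for green and -0.251 for blue. Of the 126 genes that changed at least 2-fold under full-spectrum light, 101 had the same sign in red, 103 in green and 32 in blue (80.2, 81.7 and 25.4%, against 66.4, 63 and 40.2% of all genes). Past the size rule in the same direction were 56 (red), 48 (green) and 4 (blue) of them, and past it in the opposite direction 1, 2 and 24. The blue values rest on the blue and dark labels as given: with these turned, the blue correlation would turn in sign, 4 and 24 would change places, and red and green would have another control. Genes past 2-fold under full-spectrum light, red and green in 1 direction numbered 21 (higher) and 22 (lower), and the alkaline phosphatase AW14_RS01395 was among the former, with log2 values of 1.79, 1.77 and 1.07, against -0.29 in blue.

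**Figure D3:**
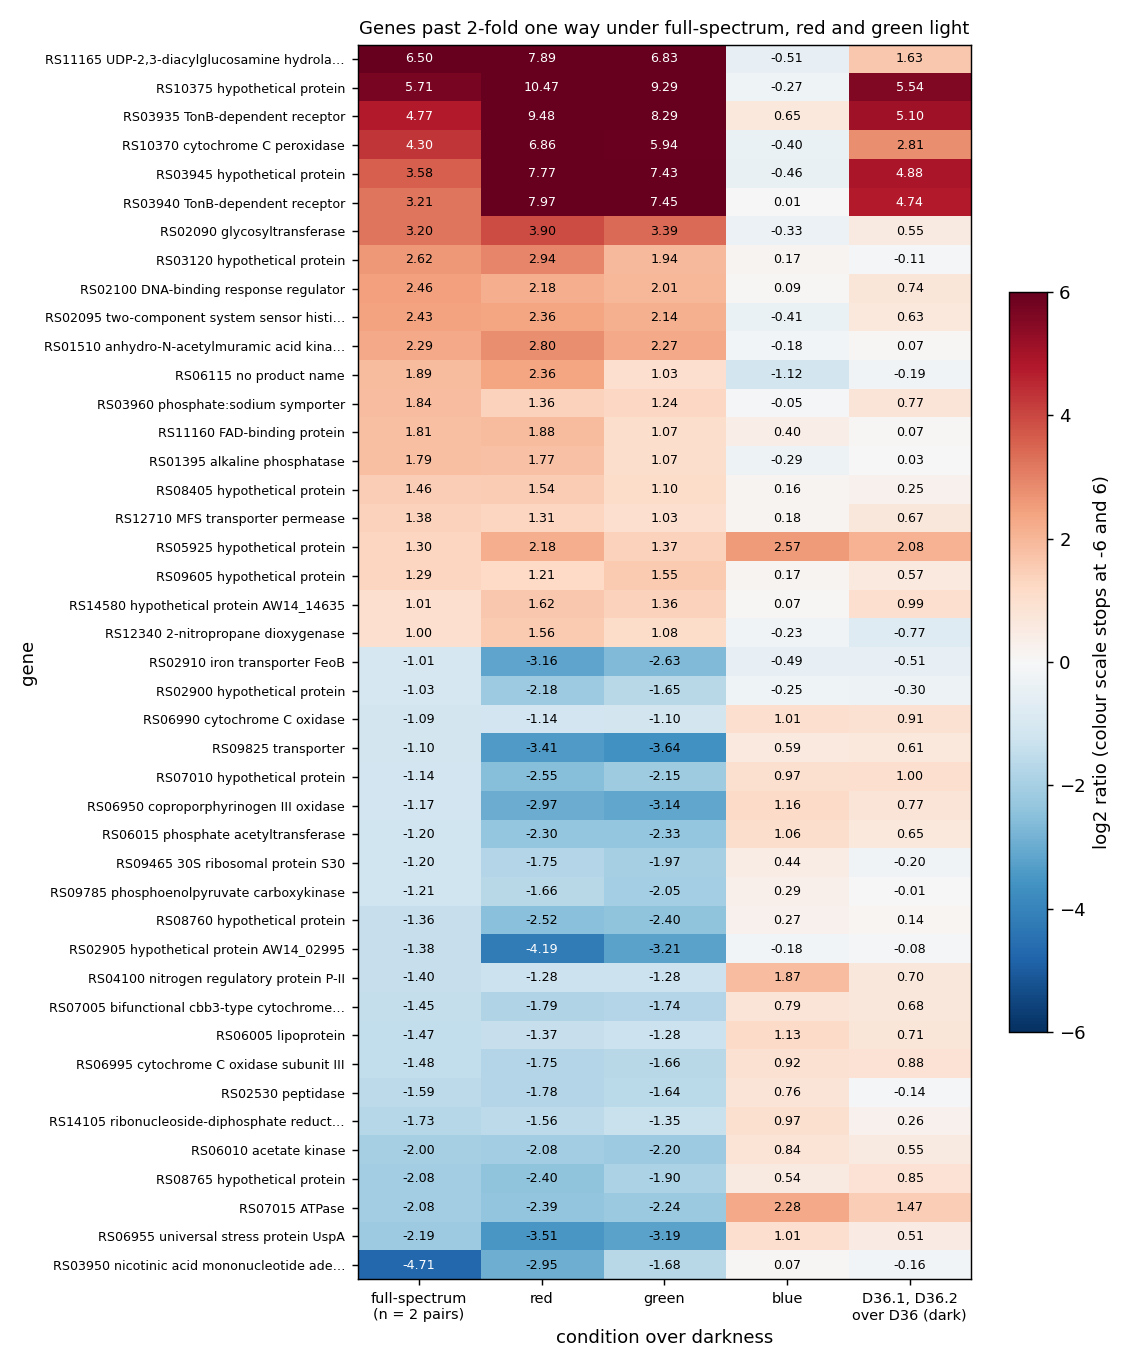
Log2 ratios (colour and printed value) of the 43 genes (y axis) past 2-fold in 1 direction under full-spectrum, red and green light (x axis: full-spectrum from 2 pairs, 1 library for each colour). The last column gives the dark libraries D36.1 and D36.2 over the dark library D36. For example, it is 5.10 at AW14_RS03935, where blue has 0.65.

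**Figure D4:**
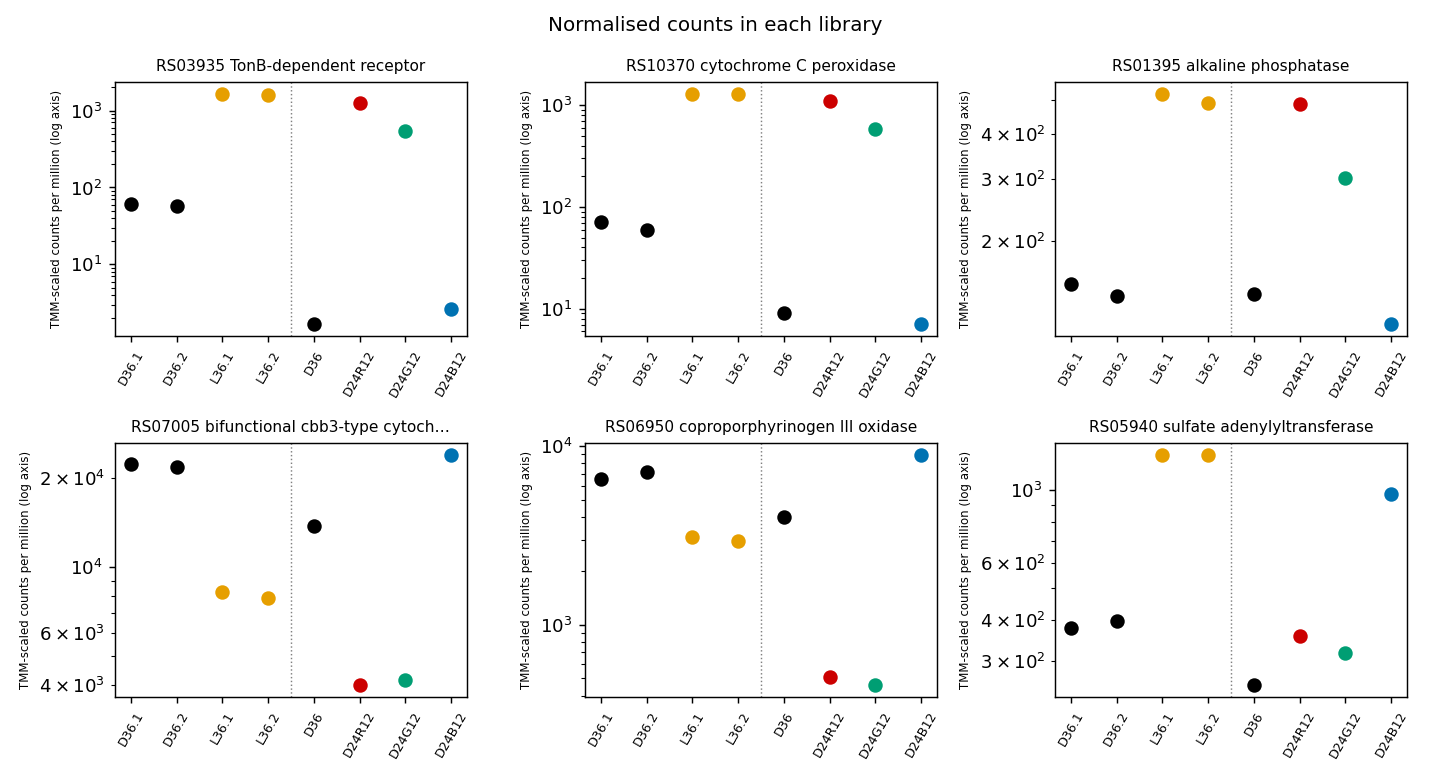
TMM-scaled CPM (y axis, log scale) in each of the 8 libraries (x axis) for 6 genes; black points are dark libraries and the dotted line parts the 2 experiments. AW14_RS03935 is low in D36 and in the blue library (D24B12), and AW14_RS06950 is low in the red and green libraries.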

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

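The tests weighed here on the blue library were all chosen after the results were seen. In 14 of the genes named above or in the plot of shared genes, both full-spectrum pairs moved at least 2-fold one way and the blue library lay at least 2-fold the other way from its dark library. In each case the difference was not tested, since blue light had 1 library. Higher in blue and lower under full-spectrum light were the ATPase AW14_RS07015 (log2 ratio 2.28 in blue, -2.05 and -2.11 in the pairs), the P-II protein AW14_RS04100 (1.87, -1.43 and -1.37) and the oxidase maturation protein AW14_RS06985 (1.4, -1.29 and -1.44). Coproporphyrinogen III oxidase AW14_RS06950 (1.16, -1.07 and -1.27) and the biotin carboxyl carrier subunit AW14_RS01690 (1.16, -1.11 and -1.53) followed. So did the lipoprotein AW14_RS06005 (1.13, -1.44 and -1.50), phosphate acetyltransferase AW14_RS06015 (1.06, -1.19 and -1.21), the stress protein AW14_RS06955 (1.01, -2.24 and -2.15) and the oxidase AW14_RS06990 (1.01, -1.06 and -1.11). Lower in blue and higher under full-spectrum light were the transporters AW14_RS12650 (-3.59, 1.25 and 1.24), AW14_RS12655 (-2.66, 1.29 and 1.31) and AW14_RS12645 (-2.51, 1.52 and 1.15). The others were sulfide:quinone reductase AW14_RS12620 (-2.91, 1.11 and 1.15) and AW14_RS06115, which has no product name (-1.12, 1.86 and 1.91).

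The pattern weighed is the difference of the blue library from its dark library, D36, which these genes share. If D36 stands apart from other dark cultures, few blue genes would pass against both other dark libraries, and 14 of 84 (16.67%) did. Red and green share D36, but against the mean of those 2 libraries they kept 104 of 141 and 56 of 75 genes, and blue 15 of 84. D36 alone therefore does not force a low share, and the 14 of 84 cannot say how much of the blue pattern comes from D36. The 14 include the sulfate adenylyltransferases AW14_RS05935 and AW14_RS05940, the ammonium transporter AW14_RS04095, the P-II protein AW14_RS04100 and the transporters AW14_RS12650 and AW14_RS12655. A swap of the blue and dark labels may also account for part of it, as the library labelled blue differed from the other dark libraries at 79 and 81 genes and the library labelled dark at 191 and 176. At AW14_RS03935 and AW14_RS03940, however, the blue library too lay far below the other dark libraries (log2 ratios -4.43 and -4.71), so neither library matched them. The experiment, a wrong label and an effect of blue light, which the design names and which stays untested, cannot be separated with 1 library each.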

How the results depend on the processing

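Chosen after seeing the data were total-read scaling and the colour experiment's dark library as the only dark library under full-spectrum light, the other experiment's dark libraries (each, or their mean) as control in the counts and lists of single colours, and red with green alone. The cause of each change below was not tested unless stated. Genes called under full-spectrum light numbered 854 in DESeq2 (431 higher, 423 lower), 134 with the colour experiment's dark library added and no block (67 each way) and 126 with a 2-fold minimum (54 higher, 72 lower). Total-read scaling gave 1189 higher and 317 lower. The labels do not say that replicate numbers mark a shared batch, and deviations of equal-numbered libraries correlated at 0.0362 across genes; without the block 1256 genes were called (646 higher, 610 lower). Leaving out a library gave 931 to 1149, with fewer samples; the lone sample left in a group was taken to vary like the others. Median-of-ratios scaling gave 1430 and the other count filters 1363 and 1373. The colour experiment's dark library as the only dark library gave 1707, with 210 of the genes called before past in the reverse direction. Of the lists, 0 were called with an estimated correlation, 1 without the block (ribosomal proteins; adjusted p = 0.0509 in camera for the respiratory, uptake, photolyase and nitrogen and sulfur lists), and 1 to 4 without a library.

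With the colour experiment's dark library added, the log2 fold change was -0.17 for AW14_RS03925, -0.067 for AW14_RS12650, -0.042 for AW14_RS12620, -0.42 for AW14_RS12605, -0.50 for AW14_RS12585, -0.36 for AW14_RS12600 and -0.14 for AW14_RS12610, each of which rose in the main comparison. Against the mean of 3 dark libraries, AW14_RS03955 had -0.89 in blue and AW14_RS12585 0.021 in red. Pairs shared 267 genes past about 1.5-fold and 27 past about 3-fold, where a stricter size keeps fewer.

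Past about 3-fold, 57 (red), 40 (green) and 26 (blue) genes passed, 38 in both red and green and 0 in all 3. Against the mean of 3 dark libraries these were 245, 146 and 43, with 129 in red and green. Against the mean of the other experiment's dark libraries red had 390 and green 261, with 225 in both and 27 in all 3. Its dark library 1 gave 401, 277, 244 and 27, and its dark library 2 gave 381, 263, 220 and 29. The blue correlation with full-spectrum light ran from -0.252 to -0.227 without a replicate. Total counts of each colour stayed within 1.5-fold under the other read minimums, scalings and pseudocounts, but higher genes numbered 107 in red and 63 in green with total-read scaling, against 68 and 31. Of the single-gene ratios given, 42 in red, 41 in green and 35 in blue left their counting interval against the mean of 3 dark libraries, as did the 2 that turned, and 5, 5 and 2 did not. The alternatives without ribosomal RNA and with another pseudocount in the full-spectrum test did not apply to these tables. Depth limits genes with few reads, such as AW14_RS07000.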

Other observations

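All tests in this part were chosen after the results were seen. The 21 genes higher and 22 lower past 2-fold under full-spectrum, red and green light had medians of -0.05 and 0.82 in blue over its own dark library, where 19 of the 22 were higher, and of -0.81 and 0.28 over the other experiment's dark libraries. Hypothetical proteins AW14_RS10375 and AW14_RS03945, singled out after their values were seen, lay beside the peroxidase and the receptors in identifier and in change (10.47 and 7.77 in red, or 6.78 and 4.52 over the mean of all 3 dark libraries). Few reads in the dark library stay open as a contribution: the lowest counting bound of the 21 genes in red and green was 0.4624, but their selection on size and reads alone keeps such bounds above 0. Library scaling moved the median of the 22 by at most 11.7% of its size, just over the tenth set as bound. A second test, added after that was seen, put the weakest median over 3 scalings at -1.777. Total-read scaling shifted the median of all genes by only 0.169 in red and 0.235 in green, and the 22 were chosen as at least 2-fold lower under TMM scaling. The test therefore argues only against the choice among these 3 scalings as the whole cause. A culture state that also varies between dark flasks may contribute. In size without sign, the dark libraries of the 2 experiments differed more at these genes than at matched random lists (percentile 100 for the 21 and 99.51 for the 22). With sign, D36.1 and D36.2 lay above D36 by a median of 0.669 at the 21 and 0.578 at the 22. Light moved the sets in opposite directions, so the dark libraries do not show 1 state that moves both sets as light did. The sets were chosen on the same dark libraries, which can raise those percentiles, and a response to light, which the design names, stays open.

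Alkaline phosphatase AW14_RS01395 and the phosphate symporter AW14_RS03960 rose under full-spectrum light and were higher in red and green, so phosphate limitation of lit cultures was tested as a hypothesis. The 9 genes with phosphate-related names had medians at percentiles of 68.9 (red) and 83.6 (green), inside the range of random lists. They include both genes that prompted the hypothesis, and also polyphosphate kinases and phosphodiesterases, whose names do not specify phosphate uptake. The percentiles therefore decide neither way.

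Light replicate 1 lay at least 2-fold below light replicate 2 at 23 genes and above it at none. The transcriptional regulator AW14_RS10660 was among them, with 32 and 315 reads against 517 and 612 in darkness. These genes had a median of 143 dark reads, against 1371 over all genes, and 16 had no informative product. Their median log2 ratio was -1.33 between the light replicates and -0.14 between the dark replicates.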
